A study of Rattus norvegicus with 4 samples.

How the data were processed

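Gene expression was measured in primary granulosa cells, the hormone-producing somatic cells of the ovarian follicle, from immature female Sprague-Dawley rats of 23 to 25 days. Per the labels' protocols, the rats had been treated with estradiol and the cells were grown in serum-free medium on dishes coated with serum. The cells were infected for 4 h with an adenovirus and then kept for 24 h with follicle-stimulating hormone (FSH) at 100 ng/ml or with vehicle, per the labels. The vectors carried green fluorescent protein (GFP) as the control, a constitutively active form of the transcription factor FOXO1 called FOXOA3, or FOXOA3-mDBD, its mutant in the DNA-binding domain. Total RNA was extracted with a column kit and labelled with biotin by the array maker's standard protocol, per the labels. There were 4 groups with 1 array each, named GFP vehicle, GFP FSH, FOXOA3 FSH and FOXOA3-mDBD FSH. Whether the RNA on an array came from 1 culture or from several, and the amount of virus used, are not given in the sources used here.

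The authors' deposited values were microarray intensity values on a linear scale, 1 per probe set and array. They had been computed with MAS5, per the submitters' processing notes, and its version and settings are not given in the sources used here. MAS5 subtracts the signal of mismatch probes and scales each array to a common trimmed mean, and its ratios are noisy for dim probe sets. The 2% trimmed means of the deposited values lay between 500.1 and 500.2 on the 4 arrays, so that no further scaling was applied. Scaling to a common mean hides any difference in total RNA per cell between groups.

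Of 31099 probe sets, 57 were controls. A table of platform annotation gave exactly 1 gene symbol for 20832 probe sets, several for 436 and none for 9780. The probe sets with several symbols or none were left unnamed. Of the identifiers, 99.7% matched a table of current rat genes, and 0 symbols needed updating. For each of the 14218 genes, the probe set with the highest mean signal over the 4 arrays was used. No genome sequence was used here, so that no positions are given.

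The floor was the median signal of the non-control probe sets pooled over the 4 arrays, 100.5. Signals under the floor were raised to it and log2 was taken. A gene counted as measured in a comparison if the higher of its 2 signals was above the floor. Where the dimmer signal was at the floor, the fold is a lower bound and is written "at least". Genes were counted as higher or lower at a fold of 2 or more.

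The comparisons were GFP FSH against GFP vehicle, FOXOA3 FSH against GFP FSH, FOXOA3-mDBD FSH against GFP FSH, and FOXOA3 FSH against FOXOA3-mDBD FSH. After the control probe sets had been seen, FOXOA3 FSH against GFP vehicle was added. With 1 array per group there was no replicate check of any difference, and no p-values were computed. The number of arrays limits the precision of every value.

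For each of 25 gene lists, the median log2 ratio of the measured members was set beside the medians of 10000 random lists of the same size. Random lists were matched on mean signal in 20 bins, and at least 5 measured members were required. A list is described as standing above or below the random lists if its median lay over the 97.5 or under the 2.5 percentile. These percentiles describe these arrays and are not a test of the treatments. The lists held 597 entries, of which 539 were named on the array. The remaining 58 were not analysed here. Some genes belong to several lists, such as Cyp11a1, Cyp19a1 and Star. The lists were cholesterol biosynthesis, SREBP regulators, cholesterol uptake, storage and efflux, steroidogenesis, fatty acid and glycerolipid synthesis, FSH-responsive granulosa genes, cAMP and growth factor early-response genes, FOXO target genes, cell cycle, glycolysis, oxidative phosphorylation, apoptosis, integrated stress and unfolded protein response, interferon response, inflammatory and NF-kB targets, TGF-beta, activin and BMP signalling, insulin and IGF signalling, reference genes, and markers of granulosa cells, theca, stroma and smooth muscle, leukocytes, endothelium, oocytes, surface epithelium and luteal cells.

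Correlations between comparisons were taken across genes, which are not independent replicates. Comparisons that share an array are correlated with no effect at all, so 50 sets of 4 unchanged arrays were simulated and their value is given beside the observed one. The noise of the simulation came from the spread between the GFP vehicle and FOXOA3 FSH arrays, with a median SD of 0.31 on the log2 scale. These arrays differ in hormone and vector, so this noise is assumed and was not measured on replicates. Shares of genes carry exact (Clopper-Pearson) binomial 95% intervals, which cover counting only.

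The steps were tested on simulated data for GFP FSH against GFP vehicle, with 9539 genes in the step and noise with an SD of 0.4 on the log2 scale. The 2-fold threshold recovered 30.6% of genes with a true fold of 1.5, 50.0% at a fold of 2, 88.0% at 3 and 93.8% at 4. It also passed 7.27% of unchanged genes. Of 200 random lists, 5.5% lay outside the central range.

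Comparisons, thresholds, lists and alternatives were fixed before the data were examined, as was the rule for named genes. The rule took, in each comparison, the 8 genes with the highest and the 8 with the lowest ratio, and up to 4 members of each list that were 2-fold apart. For cholesterol biosynthesis, SREBP regulators, steroidogenesis and FSH-responsive genes it took up to 4 in each direction, and Foxo1 on every array. A gene named in 1 comparison may be given in the others, and not every list member that the rule took is printed: for length, many members of lists inside the random range were left out, and these were not always those with the smallest ratios. The plot of signals shows, of each of 4 lists, the 6 members with the widest range of signals over the arrays, a rule set after the data were seen.

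The alternatives were the 25th percentile as the floor, the floor value as a pseudocount, quantile normalization, centring on the median, intensity-dependent loess (span 0.4), a filter at the 75th percentile, the mean of a gene's probe sets, leaving out probe sets whose design allows cross-hybridisation, and a 3-fold threshold. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.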

Results

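Expression was profiled on 4 rat arrays, 1 for each of GFP vehicle, GFP FSH, FOXOA3 FSH and FOXOA3-mDBD FSH. Of the rat probe sets, 49.6%, 47.9%, 52.8% and 49.7% had a signal above the floor on these arrays in that order. Foxo1 itself, read by its brightest probe set, had a signal of 8149 on GFP vehicle, 2862 on GFP FSH, 3834 on FOXOA3 FSH and 961 on FOXOA3-mDBD FSH. The species of the transgenes and the part of the transcript that this probe set covers are not given in the sources used here, so these signals do not check the vectors.

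The arrays fell into a pair of groups by their control transcripts. The poly-A spike transcripts, bacterial RNAs that are added to a sample before labelling, had a geometric mean signal of 394.6 on GFP FSH and 539.4 on FOXOA3-mDBD FSH. On GFP vehicle and FOXOA3 FSH it was 21.4 and 22.6. Hybridisation controls were at 1647, 2759, 1224 and 2855 on GFP vehicle, GFP FSH, FOXOA3 FSH and FOXOA3-mDBD FSH. The ratio of 3' to 5' signal of beta-actin was 5.15, 12.0, 9.79 and 10.7 in the same order, and that of GAPDH 2.32, 2.46, 2.84 and 3.15. FOXOA3-mDBD FSH against GFP FSH and FOXOA3 FSH against GFP vehicle therefore each compare arrays with the same spike state, and the other 3 comparisons cross it.

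**Figure D1:**
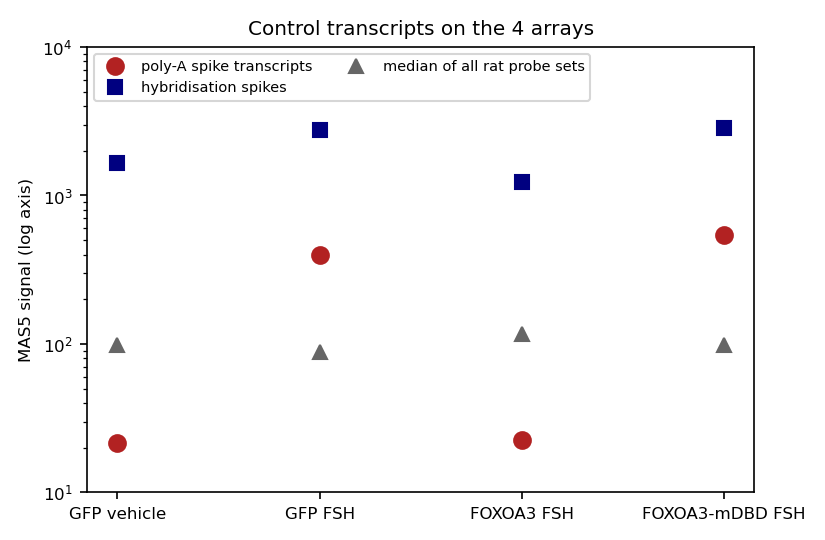
MAS5 signal on a log axis for each of the 4 arrays: the geometric mean of the poly-A spike probe sets (circles), that of the hybridisation controls (squares) and the median of all rat probe sets (triangles). The poly-A spikes stood at 394.6 and 539.4 on GFP FSH and FOXOA3-mDBD FSH and at 21.4 and 22.6 on GFP vehicle and FOXOA3 FSH.

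The series title concerns the regulation of sterol, steroid and lipid synthesis genes by FSH and FOXO1, and GFP FSH against GFP vehicle gives the response to the hormone. Cyp11a1, the enzyme that cleaves the side chain of cholesterol, was 131-fold higher with FSH, and Cyp19a1, the aromatase that makes estrogen, was at least 129.8-fold higher. Star, which carries cholesterol into mitochondria, was 48.9-fold higher, the prolactin receptor Prlr at least 50.2-fold and the luteinizing hormone receptor Lhcgr at least 43.8-fold. The stress-responsive mTORC1 inhibitor Ddit4 was 60.0-fold higher, Fam110c at least 46.1-fold and G0s2, an inhibitor of triglyceride lipase, at least 39.4-fold. At the other end, Tnfrsf11b, the decoy receptor osteoprotegerin, was lower with a log2 ratio of -6.61 or below, and the sphingosine 1-phosphate receptor S1pr1 44.6-fold lower. Pamr1 was at least 45.8-fold lower, the angiotensin receptor Agtr2 at least 40.2-fold, Lrrfip1 26.1-fold, the aminopeptidase Anpep at least 25.8-fold and Arhgap6 24.7-fold.

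All but 1 of the 18 measured cholesterol biosynthesis genes had a higher signal with FSH, and 16 were at least 2-fold higher. Their median log2 ratio was 1.77, above the range of matched random lists of -0.24 to 0.43. Hsd17b7, a sterol ketoreductase, was 8.29-fold higher, the sterol reductases Tm7sf2 and Dhcr7 6.27-fold and 5.84-fold, and the isoprenoid isomerase Idi1 5.89-fold. Among the SREBP regulators, Srebf1 was 2.42-fold higher and Insig1, which retains the SREBP complex in the endoplasmic reticulum, 2.19-fold higher, while Nfya, a subunit of the CCAAT-binding factor, was 2.99-fold lower. With these 2 of 12 higher and 1 lower, the list median of 0.12 lay inside the random range. The receptor Scarb1, which takes up cholesteryl esters from high-density lipoprotein, was 28.8-fold higher and the lipoprotein receptor Lrp8 8.03-fold, whereas Cav1, the main protein of caveolae, was 20.9-fold lower. Uptake, storage and efflux genes had a median of 0.33, inside the random range, with 5 of 16 members higher, among them Stard4 at 3.54-fold, and 5 lower.

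Of 15 measured steroidogenesis genes, 11 were higher and 1 lower, with a median of 2.02. Fdx1, the electron donor of mitochondrial P450 enzymes, was 9.22-fold higher, and the nuclear receptor Nr0b1 was 6.13-fold lower. FSH-responsive granulosa genes had a median of 1.57 (17 of 28 higher, 2 lower) and the lower members were Akap12, a scaffold of protein kinase A, at 13.0-fold, and Dab2 at 8.33-fold. Fatty acid and glycerolipid genes had a median of 0.72, with 10 of 26 higher and 0 lower, among them the desaturase Scd at 6.76-fold, the elongase Elovl6 at 3.35-fold, Acsl3 at 3.25-fold and the malic enzyme Me1 at 2.93-fold. Granulosa cell markers (median 0.92) and luteal markers (1.25) also stood above random lists, as did cell cycle (0.77), glycolysis (0.83) and the integrated stress and unfolded protein response (0.55). Nppc, the precursor of C-type natriuretic peptide, was at least 10.6-fold higher, Hsd17b1 6.29-fold and Nr5a2 4.90-fold, in a granulosa list with 8 of 17 higher and 1 lower. Of the luteal markers 6 of 11 were higher and 2 lower, with Rgs2 3.20-fold higher. Of the cell cycle genes, 9 of 36 were 2-fold higher, with the spindle checkpoint kinase Bub1b at 5.29-fold, Ccnb2 at 2.68-fold and Aurka at 2.56-fold, and 1 was lower, Ccnd3 at 2.59-fold. Glycolysis had 7 of 17 higher and 2 lower, with Pfkm 2.91-fold and Slc16a1 2.40-fold higher, and Pfkl 2.62-fold and Pdk1 2.33-fold lower. In the stress response 7 of 24 were higher and 3 lower. Its largest ratio was that of Nupr1, 7.46-fold lower, and Slc7a11 was 4.58-fold higher, Asns 4.05-fold and Herpud1 2.72-fold. The epidermal growth factor-like ligands Areg and Ereg were 24.4-fold and at least 7.52-fold higher and the phosphodiesterase Pde4b 5.63-fold, while Klf6, an early-response factor, was 9.65-fold lower. With 7 of 23 early-response genes higher and 4 lower, the list did not stand apart.

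Lists below random lists were FOXO target genes (median -0.29, 10 of 30 lower and 3 higher, but inside the range under the 75th percentile filter or the mean of probe sets), insulin and IGF signalling (-0.57, 7 of 20 lower and 0 higher) and theca, stroma and smooth muscle markers (-0.82, 5 of 14 lower and 0 higher). The theca and stroma median ran from -3.40, with the 8 members past the 75th percentile filter, to -0.44 under the 25th percentile floor. Within the FOXO targets, Pik3ip1, an inhibitor of PI3-kinase, was 10.6-fold lower and Gadd45b 7.21-fold lower, while Ddit4 and the selenium carrier Selenop, at 8.42-fold, were higher. Irs2, an adaptor of the insulin receptor, was 6.61-fold lower, Igf1 3.11-fold, Foxo1 2.85-fold and Tsc2 2.52-fold. Smooth muscle actin Acta2 was 19.3-fold lower, the collagen Col3a1 15.3-fold, fibronectin Fn1 13.4-fold and Aspn at least 10.9-fold. Among members of lists inside the random range, Tgfbi was at least 14.6-fold higher, Bmp4 was 13.0-fold lower and Tgfb2 9.79-fold. Medians inside the random range were those of early-response genes (-0.01), oxidative phosphorylation (0.25), apoptosis (-0.13), interferon response (0.24), inflammatory targets (-0.02), TGF-beta signalling (-0.21), leukocyte (0.05) and endothelial markers (-0.06) and reference genes (0.27). Oocyte and surface epithelium markers had too few measured members in every comparison. In total, 655 of 9578 measured genes were 2-fold higher and 1063 were lower, against 304 genes 2-fold apart between simulated unchanged arrays. That number depends on the noise assumed: the self-test, with a noise SD of 0.4 in place of a median of 0.31, passed 7.27% of 9539 unchanged genes. This comparison crosses the spike state of the arrays, and all later comparisons with GFP FSH use the same array. The beta-actin 3' to 5' ratio also differed, at 5.15 on GFP vehicle and 12.0 on GFP FSH, and that of GAPDH was 2.32 and 2.46. The beta-actin ratio did not follow the spike state, since it was 9.79 on FOXOA3 FSH and 10.7 on FOXOA3-mDBD FSH.

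**Figure D2:**
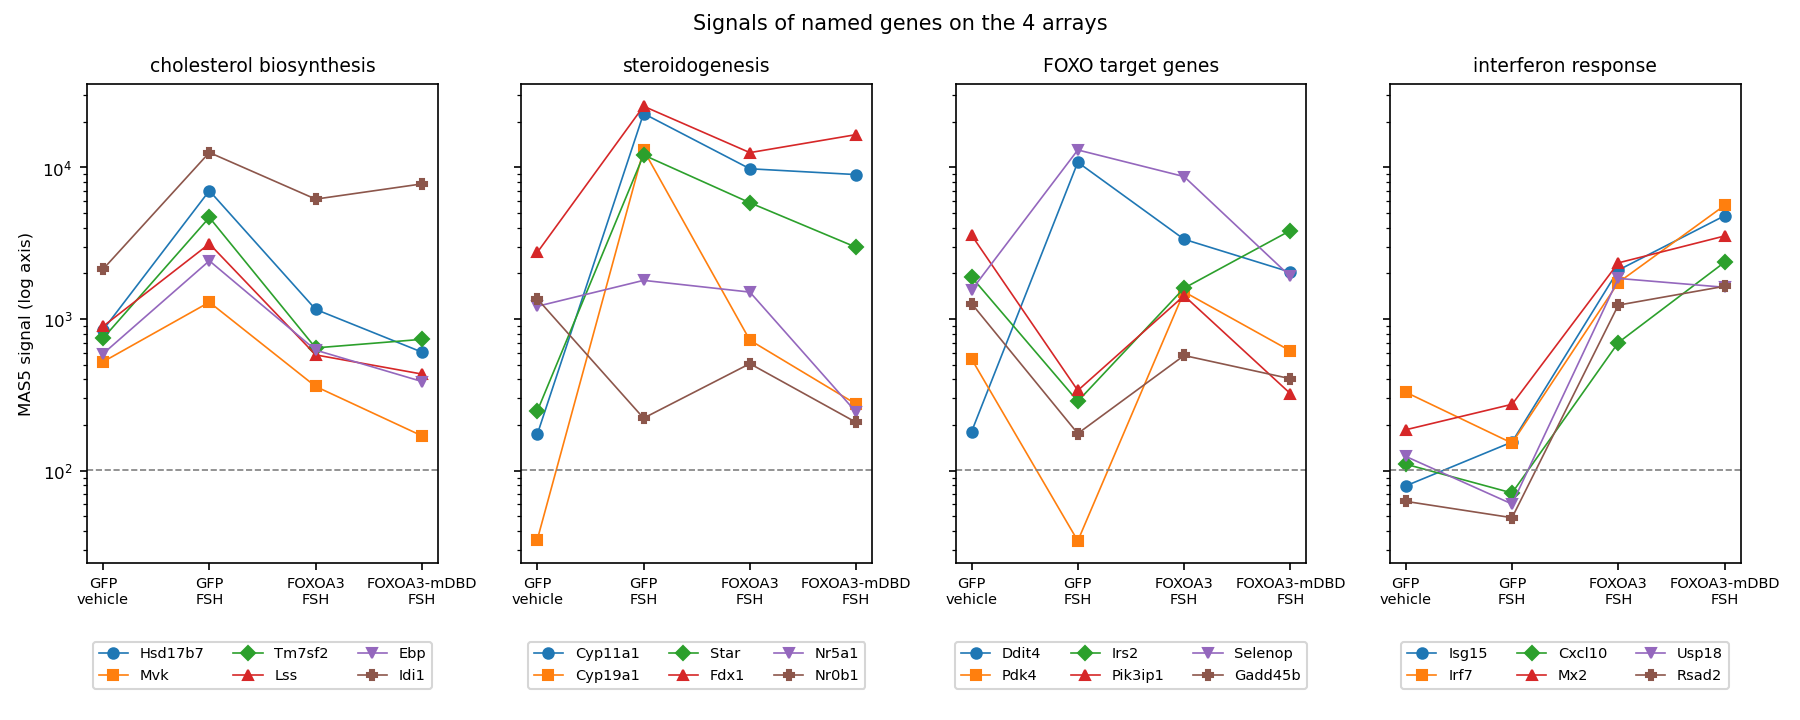
MAS5 signals on a log axis on the 4 arrays for the 6 members with the widest range in each of 4 gene lists; lines join the signals of a gene and the dashed line is the floor of 100.5. Cyp11a1 stood at 174, 22700.1, 9809 and 8979 from left to right, and the interferon genes shown were brightest on the 2 arrays with a FOXO1 vector.

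FOXOA3 FSH against GFP FSH sets active FOXO1 against the control vector in FSH-treated cells. Cyp19a1 was 18.0-fold lower with FOXOA3 and Lhcgr 8.85-fold lower, and 17 of 18 cholesterol biosynthesis genes were at least 2-fold lower. Tm7sf2 was 7.25-fold lower, Hsd17b7 6.07-fold, the lanosterol synthase Lss 5.41-fold and the sterol dehydrogenase Nsdhl 5.21-fold. The list median was -1.84, below the random range of -0.45 to 0.27. Higher with FOXOA3 were Tspan8, a tetraspanin, by at least 78.0-fold, Pamr1 by at least 62.5-fold, the cannabinoid receptor Cnr1 by at least 46.4-fold, the angiotensin receptor Agtr2 by at least 37.4-fold, Tnfrsf11b by at least 37.0-fold and Igsf1 by 32.5-fold. Lower were Tmem252 by at least 8.24-fold, Asphd2 by 7.44-fold, the mitotic kinase Pbk by 6.95-fold and Pclaf by 6.70-fold.

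Steroidogenesis genes had a median of -0.90, with 8 of 16 lower and 2 higher, and FSH-responsive genes had a median of -1.02, with 14 of 27 lower and 2 higher. Hsd17b1, which converts estrone to estradiol, was 4.38-fold lower, Prlr 4.17-fold, Hsd11b2 3.53-fold, Tspo 2.75-fold, Cyp11a1 2.31-fold and Star 2.07-fold. Higher members were Akap12 at 6.46-fold, Dab2 at 4.08-fold, Cyp1b1 at 3.29-fold and Nr0b1 at 2.29-fold. Srebf1 was 3.26-fold lower and Insig1 3.11-fold, but Nfya was 2.98-fold higher. With 1 of 12 higher and 2 lower, the SREBP regulators as a list, at -0.26, lay inside the random range. Fatty acid genes had a median of -0.88 (12 of 26 lower, 1 higher), with Elovl6 6.28-fold lower, the acetyl-CoA synthetase Acss2 5.26-fold, Mid1ip1 3.54-fold and Fads1 3.54-fold. Uptake, storage and efflux genes had a median of -0.43, which stood below random lists here but not under quantile normalization, centring or loess (-0.19). The list had 6 of 16 members lower, among them Lrp8 at 4.86-fold, Stard4 at 3.89-fold and Scarb1 at 2.68-fold, and 3 higher, led by Cav1 at 8.15-fold.

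Cell cycle genes had a median of -1.15, with 22 of 36 lower and 1 higher. Cyclin A2 (Ccna2) was 6.64-fold lower, the mitotic kinase Aurkb 4.94-fold and Cdk1 4.21-fold, and Bub1b was lower with a log2 ratio of -2.68 or below. Glycolysis (-0.83) and granulosa cell markers (-1.02) also stood below random lists, with 7 of 17 glycolysis genes and 9 of 17 granulosa markers lower and 0 higher. The granulosa median was -0.37 under both quantile normalization and loess, still below random lists. Nppc was 5.74-fold lower, Amhr2 2.71-fold, Pfkm 3.22-fold, Aldoc at least 3.17-fold, Gpi 2.41-fold and Tpi1 2.38-fold. FOXO target genes stood above them with a median of 0.68, with 10 of 29 higher and 2 lower. Pdk4, the kinase that inhibits pyruvate dehydrogenase, was at least 15.1-fold higher, Irs2 5.58-fold, Sesn3 at least 4.57-fold and the transcription factor Klf2 4.28-fold, while Ddit4 was 3.22-fold lower.

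Interferon response genes had a median of 1.20, with 14 of 25 higher and 0 lower. The ubiquitin-like modifier Isg15 was 13.6-fold higher, its protease Usp18 at least 18.5-fold, the antiviral enzyme Rsad2 at least 12.3-fold and the transcription factor Irf7 11.5-fold. Theca, stroma and smooth muscle markers had a median of 1.22 with 8 of 15 higher and 2 lower, Ogn and Lum. It ran from 0.93 under the 25th percentile floor to 3.17 with the 8 members past the 75th percentile filter. The higher members included Col3a1 at 44.4-fold, Aspn by at least 32.9-fold, the proteoglycan decorin (Dcn) at 25.8-fold and Fn1 at 22.5-fold. Inflammatory targets had a median of 0.58, above random lists in this setting but inside their range under 5 of the 8 alternatives. Nfkbiz was at least 5.91-fold higher and Relb 2.27-fold, and Lcn2 was at least 2.49-fold lower, with the other 10 of its 13 members within 2-fold. Medians inside the random range were those of early-response genes (0.24), oxidative phosphorylation (-0.40), apoptosis (0.02), the stress response (0.25), TGF-beta signalling (0.03), insulin signalling (0.26), leukocyte (0.31), endothelial (0.72) and luteal markers (-0.09) and reference genes (-0.61). Among members of these lists, Klf6 was 8.94-fold higher, Cebpb 5.33-fold and Acvr2a 4.09-fold, and Tgfbi was 4.65-fold lower and Bmpr2 4.29-fold. In all, 1105 of 9941 genes were higher and 695 lower, and the comparison crosses the spike state. Under quantile normalization 915 were higher and 826 lower, with loess 963 and 741, and with centring 1027 and 758.

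FOXOA3-mDBD FSH against GFP FSH asks the same of the mutant that is defective in DNA binding, on arrays with the same spike state. Cholesterol biosynthesis genes were lower here too, with a median of -2.19 and 16 of 18 members lower. This comparison uses the same GFP FSH array as the 2 before it, so the shifts of these genes are not independent. Hsd17b7 was 11.6-fold lower, mevalonate kinase Mvk 7.62-fold, Lss 7.24-fold and Tm7sf2 6.37-fold. Cyp19a1 was 47.5-fold lower, Lhcgr 23.7-fold and Ass1, an enzyme of arginine synthesis, at least 24.2-fold. Among the higher genes were sciellin (Scel) by at least 152-fold, Aspn by at least 115-fold, the Notch target Hey1 at 112-fold, Ranbp17 by at least 97.0-fold, the protocadherin Pcdh20 by at least 89.6-fold, Arhgap24 by at least 70.0-fold, the ephrin receptor Epha4 by at least 69.2-fold and Chodl by at least 67.6-fold. Asphd2 was at least 19.1-fold lower, the protease Mmp11 18.9-fold, Selenbp1 18.7-fold, Crym 16.8-fold and Acsbg1 16.2-fold.

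Steroidogenesis genes had a median of -1.53 (11 of 15 lower, 1 higher). The steroidogenic factor Nr5a1 was 7.41-fold lower, the mitochondrial translocator Tspo 6.42-fold, Hsd11b2 at least 5.58-fold, Star 4.06-fold and Cyp11a1 2.53-fold, and the higher member was Cyp1b1 at 4.49-fold. SREBP regulators had a median of -0.93, with Srebf1 7.25-fold lower, Insig1 3.86-fold, Srebf2 3.09-fold and Sp1 2.32-fold, and with 5 of 12 lower and 0 higher. Also below random lists were FSH-responsive genes (-1.37, 15 of 26 lower and 1 higher), fatty acid genes (-0.93, 12 of 26 lower and 1 higher), and uptake, storage and efflux genes (-0.94, 8 of 16 lower and 2 higher). The same held for cell cycle (-1.10, 20 of 36 lower and 2 higher), glycolysis (-0.90, 8 of 18 lower and 0 higher), granulosa cell markers (-1.53, 12 of 19 lower and 2 higher) and luteal markers (-0.99, 5 of 11 lower and 0 higher). The largest ratio of the uptake genes ran against the list, with Cav1 27.8-fold higher, while Lrp8 was 6.26-fold lower, Scarb1 5.21-fold and Stard4 4.47-fold. Kitlg, the ligand of the Kit receptor, was the FSH-responsive gene that was higher, at 3.72-fold. The desaturases Fads1 and Fads2 were 7.15-fold and at least 5.78-fold lower, the fatty acid synthase Fasn 5.54-fold and Elovl6 5.27-fold. Inhibin alpha (Inha) was 6.93-fold lower, the transcription factor Gata4 10.5-fold, Nppc at least 10.6-fold, Prlr 5.45-fold and Sparc 3.20-fold. Topoisomerase Top2a was 6.07-fold lower, Ccna2 5.66-fold, Ccnd2 5.63-fold and Cdk1 3.97-fold, and of the glycolysis genes Gpi was 4.99-fold lower, Aldoa 3.38-fold, Hk1 3.10-fold and Pfkfb4 2.70-fold.

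Interferon response was the only list above random lists, with a median of 1.38 and 14 of 25 members higher, led by Irf7 at 37.0-fold, Isg15 at 31.1-fold, the chemokine Cxcl10 by at least 23.6-fold and Rsad2 by at least 16.4-fold. FOXO target genes had a median of 0.04, inside the random range, with 6 of 29 higher and 5 lower. Irs2 was 13.4-fold higher and Pdk4 at least 6.14-fold, while Selenop was 6.84-fold lower and Ddit4 5.31-fold. Medians inside the range were also those of early-response genes (-0.31), oxidative phosphorylation (-0.43), apoptosis (-0.69), the stress response (0.07), inflammatory targets (-0.58), TGF-beta (-0.21) and insulin signalling (0.24), theca and stroma (-0.53) and leukocyte markers (0.21) and reference genes (-0.14). Of the theca and stroma markers Aspn was the only one higher and 5 of 12 were lower, with Ogn 3.90-fold lower, Col5a1 2.63-fold and Dcn 2.36-fold. Among members of the other lists, Tgfbi was at least 14.6-fold lower, Igfbp5 14.3-fold and Ereg at least 7.52-fold, and Acvr2a was 8.36-fold higher. In this comparison 1221 of 9748 genes were higher and 1865 lower, around a median of all genes of -0.16, to which the ratios above are to be read. With centring on that median, 1517 were higher and 1465 lower, and with loess 1573 and 1355.

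With both vectors set against GFP FSH, 392 of 9402 genes were 2-fold higher with each and 467 were lower with each. Independent lists of these sizes would share 120 and 138, but comparisons that share an array are not independent. Simulated unchanged arrays shared 25.9 and 31.4, but with only 151 to 152 genes in each direction of each comparison. The observed lists held 1015 and 1109 higher genes and 695 and 1865 lower ones. Neither number is thus a fit baseline for 392 and 467. The ratios correlated at r = 0.54 across genes, against 0.50 for simulated unchanged arrays, and their covariance was 0.503 against 0.105. The simulated covariance depends on the noise assumed. Both comparisons use the single GFP FSH array, so part or all of the overlap may come from it.

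FOXOA3 FSH against FOXOA3-mDBD FSH bears on which differences depend on the DNA-binding domain. Cholesterol biosynthesis genes differed little between the vectors, with a median of 0.28 inside the random range and only Mvk, at 2.12-fold higher with FOXOA3, past 2-fold. Among the genes higher with FOXOA3 were the collagen Col3a1 by at least 75.2-fold, the matricellular protein Ccn3 at 61.9-fold, Dcn at 60.8-fold, Pamr1 at 33.5-fold, Igsf1 at 29.7-fold, Tspan8 at 29.2-fold, the protease Adamts5 at 23.8-fold and Fn1 at 16.1-fold. Lower with FOXOA3 were Ranbp17 at 58.0-fold, the sodium channel Scn1a by at least 40.0-fold, the dopamine receptor Drd4 by at least 37.3-fold, the forkhead factor Foxq1 by at least 35.7-fold, Tox3 by at least 35.2-fold, Tchh by at least 33.9-fold, Cbln1 by 33.9-fold and Scel by 33.8-fold.

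FOXO target genes had a median of 0.59, above random lists, with 11 of 30 higher and 2 lower. Klf2 was 4.65-fold higher, Selenop 4.56-fold, Pik3ip1 4.43-fold and Sesn3 3.52-fold, and Irs2 was 2.40-fold lower. The FOXO target list stood apart only in the 3 comparisons that cross the spike state (-0.29, 0.68 and 0.59). It was higher on the spike-free array each time. Within a spike state it was inside the random range, at 0.04 and 0.07. For this list, a difference in labelling cannot be told apart from effects of FSH and FOXOA3. Steroidogenesis genes had a median of 0.66 (6 of 16 higher, 0 lower), which stood above random lists here but inside their range under quantile normalization, the pseudocount and the 75th percentile filter. Nr5a1 was 6.20-fold higher, Cyp19a1 2.64-fold, Hsd11b1 2.64-fold and Nr0b1 2.44-fold. Granulosa cell markers (0.71, 7 of 19 higher and 2 lower) and theca, stroma and smooth muscle markers (1.33, 9 of 15 higher and 1 lower) stood above random lists. Foxl2 was 4.32-fold higher, Gata4 4.27-fold, Serpine2 3.33-fold and Tagln 4.45-fold, and Kitlg was 2.74-fold lower. The theca and stroma list too stood apart only across the spike state (-0.82, 1.22 and 1.33), each time higher on the spike-free array. Within a spike state it was inside the random range, at -0.53 and 0.19. Labelling cannot be told apart from the treatments for this list either. The stress response (0.60) stood above random lists in this setting but not under 5 of 8 alternatives (0.15 under loess). Of its members, 5 of 25 were higher, among them Atf5 at 2.85-fold, Pdia4 at 2.36-fold, Sdf2l1 at 2.27-fold and Nupr1 at 2.16-fold, and 0 were lower.

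Interferon genes had a median of -0.17, below random lists here but not under loess, the 25th percentile floor or the 75th percentile filter, with 6 of 25 lower and 1 higher. The median was -0.37 under centring and -0.40 under loess. Ifit3 was 3.65-fold lower, the RNA sensor Ifih1 3.61-fold, Cxcl10 3.39-fold and Irf7 3.23-fold. Cell cycle genes had a median of -0.09, below random lists, but it ran from -0.55 under loess to 0.015 under the 75th percentile filter, where the list lay inside their range, and 6 of 36 were 2-fold higher and 4 lower. Rrm1 was 4.34-fold lower, and Cdk2 was 2.70-fold higher and Ccnd3 2.51-fold, as was Ccnd2 with a log2 ratio of 1.32. Lists inside the random range were SREBP regulators (0.46), uptake genes (0.42), fatty acid genes (0.16), FSH-responsive genes (0.43), early-response genes (0.35), glycolysis (0.39), oxidative phosphorylation (-0.05), apoptosis (0.41), inflammatory targets (0.60), TGF-beta (0.56) and insulin signalling (0.37), leukocyte (0.27), endothelial (0.39) and luteal markers (0.84) and reference genes (-0.34). The early-response factor Cebpb was at least 27.6-fold higher with FOXOA3, Akap12 at least 7.83-fold, Igfbp4 6.28-fold, Apoe 3.49-fold and Nfya 3.07-fold, and Smad7 was 5.21-fold lower, Igf1 4.54-fold and Cav1 3.41-fold. Of 10092 genes, 1913 were higher and 932 lower, around a median of all genes of 0.21, and the comparison crosses the spike state. With centring on that median, 1315 were higher and 1319 lower, and with loess 1076 and 1281.

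The response to FSH was set against this contrast, which uses the other 2 arrays. Across 9263 genes the ratios correlated at r = -0.26 (Spearman -0.30), and unchanged arrays gave 0. Of the genes lower with FSH, 853 of 1047 measured were higher with FOXOA3 than with FOXOA3-mDBD (81.5%, interval 79.0 to 83.8), against 60.2% of all genes. Of the genes higher with FSH, 270 of 634 were lower with FOXOA3 than with the mutant (42.6%, 38.7 to 46.5), against 39.7% of all genes. The 42.6% share was 52.1% under centring and 55.7% under loess, but so scaled 50% and 49.5% of all genes were lower. It is to be read against the share of all genes in the same setting, and was 43.2% against 45.2% under the 75th percentile filter, so that its small excess did not hold in every setting. Each of these 2 comparisons sets a spike-bearing array against a spike-free one, and they do so in opposite directions. A labelling effect alone could thus give a negative correlation and raise the 81.5% share, and the simulated value of 0 holds no such effect. The other pair of comparisons without a shared array was FOXOA3-mDBD FSH against GFP FSH and FOXOA3 FSH against GFP vehicle. Each lies within a spike state, and their ratios correlated at r = 0.27 across 9245 genes.

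FOXOA3 FSH against GFP vehicle, the comparison added after the controls were seen, sets together arrays that share a spike state but differ in both hormone and vector. Their beta-actin 3' to 5' ratios differed too, at 9.79 and 5.15. Cyp11a1 was 56.5-fold higher in FOXOA3 FSH, Star 23.7-fold, Prlr at least 12.0-fold, Scarb1 10.7-fold and Cyp19a1 at least 7.22-fold, and the steroidogenesis median of 0.75 stood above random lists, with 6 of 16 higher and 1 lower. Hsd11b1 was at least 5.31-fold higher, and the lower member was Nr0b1 at 2.68-fold. Cholesterol biosynthesis genes had a median of -0.09, inside the random range of -0.23 to 0.20, with only Idi1, at 2.90-fold higher, past 2-fold. Interferon genes had a median of 1.17 with 15 of 25 higher and 0 lower, including Isg15 by at least 20.9-fold, Usp18 at 14.9-fold, Mx2, an antiviral GTPase, at 12.6-fold and Rsad2 by at least 12.3-fold. Tspan8 was 57.6-fold higher, Igsf1 28.7-fold, Cnr1 26.2-fold, Nap1l5 at least 23.4-fold, the relaxin gene Rln1 21.4-fold and Sfrp2 at least 21.0-fold. Mcam, a cell adhesion molecule, was 10.3-fold lower, S1pr1 9.17-fold, Fbln5 8.98-fold, Rcan2 7.96-fold, Tnnc1 at least 7.81-fold, P4ha3 7.30-fold, Ptges 7.09-fold and Septin4 7.01-fold.

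FSH-responsive genes (0.51), early-response genes (0.31), the stress response (0.51), inflammatory targets (0.62) and luteal markers (0.91) also stood above random lists, the early-response genes not under the 75th percentile filter (0.02). The FSH-responsive list had 11 of 28 higher and 3 lower, Krt8 at 2.26-fold, Dab2 at 2.04-fold and Akap12 at 2.02-fold. Areg was 11.0-fold higher, Pde4b 5.22-fold, Ptgs2 at least 4.04-fold, Cebpb 3.27-fold, Nfkbiz 2.68-fold, Sod2 2.23-fold, Lhcgr at least 4.95-fold and Sfrp4 at least 4.37-fold. The cystine transporter Slc7a11 was 5.53-fold higher, the serine synthesis enzyme Psat1 4.35-fold, asparagine synthetase Asns 3.75-fold and Mthfd2 3.06-fold. Cell cycle (-0.24) and insulin signalling genes (-0.25) stood below random lists, neither under the 75th percentile filter and the insulin list not under loess, with 3 of 36 and 4 of 22 members lower and 0 and 1 higher. Cdk1 was 3.07-fold lower, Aurkb 2.75-fold, Ccna2 2.62-fold, Igf1 4.63-fold, Pik3r1 at least 3.41-fold and Igfbp5 2.27-fold, and Igfbp6 was 2.30-fold higher. All other lists lay inside the range, among them FOXO target genes at 0.07, fatty acid genes at 0.03 and granulosa cell markers at 0.20. Within these, Dcn had a log2 ratio of 4.32, Ddit4 was 18.6-fold higher and Selenop 5.62-fold, and Bmp4 was 6.63-fold lower, Acta2 6.25-fold, Acss2 3.61-fold and Vldlr 3.09-fold. This pair of arrays was the closest, with 527 of 9904 genes higher and 397 lower. Under the 25th percentile floor, which admits more genes, 1237 of 12612 were higher and 609 lower.

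**Figure D3:**
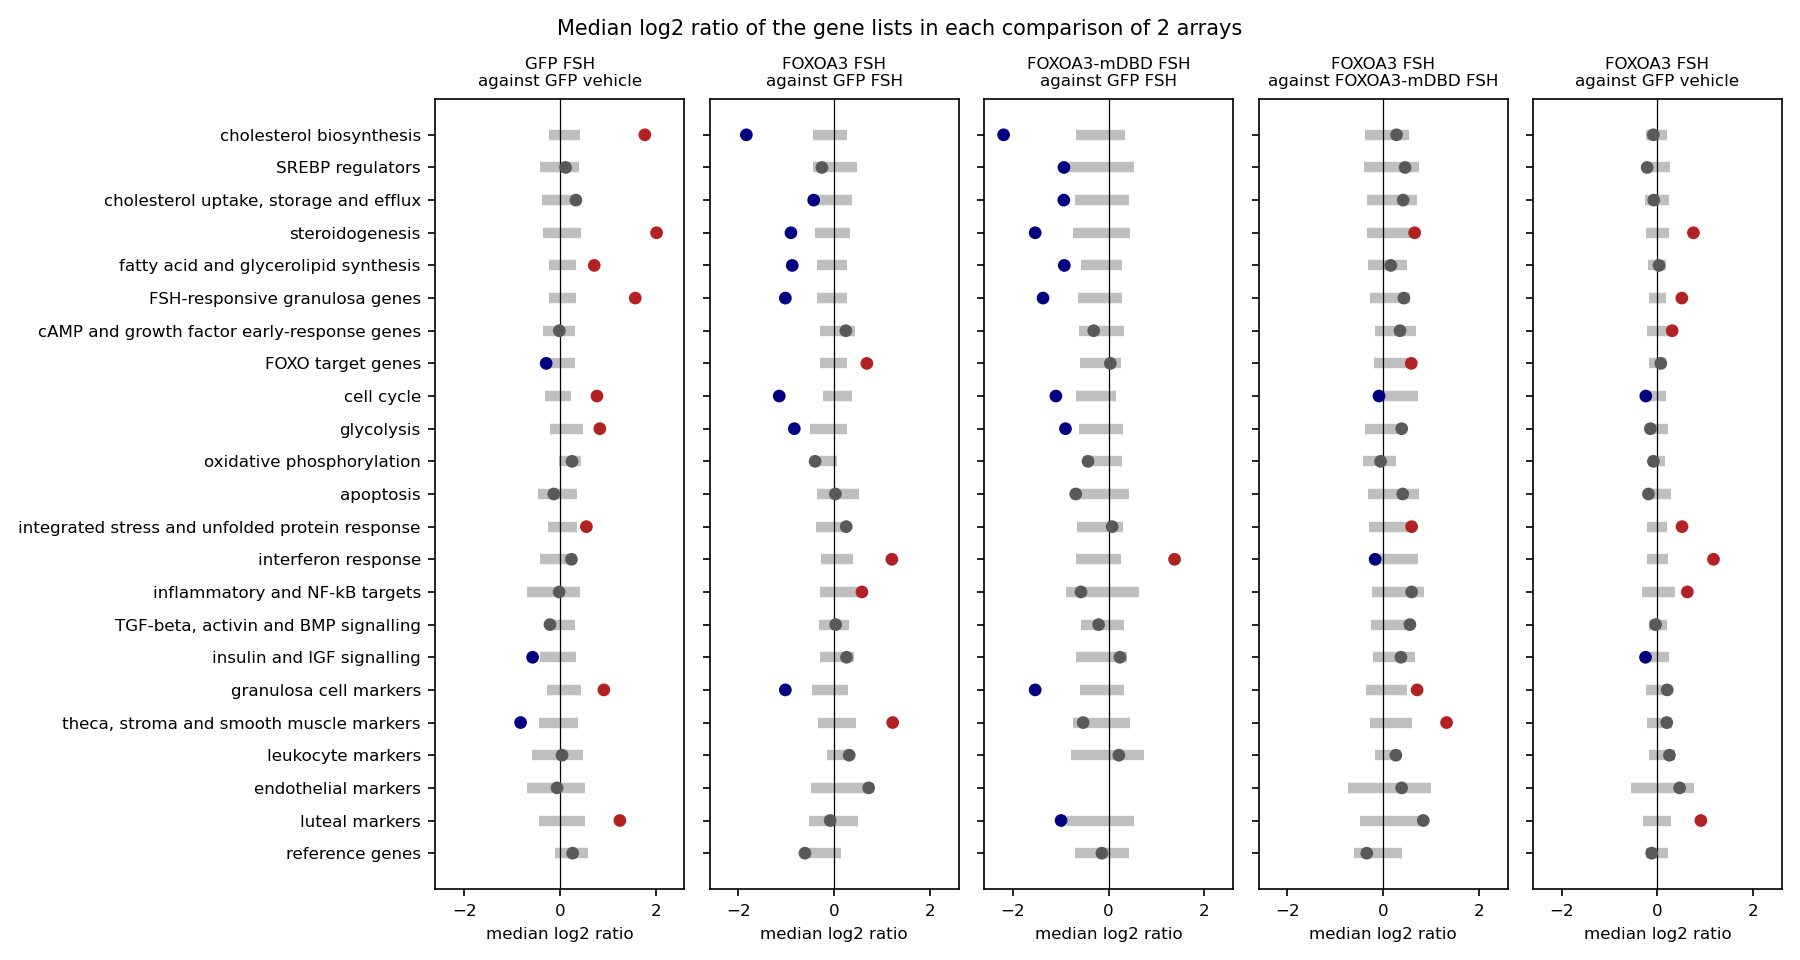
Median log2 ratio (points, horizontal axis) of each gene list in the 5 comparisons; grey bars are the central 95% of medians of matched random lists, red and blue points lie above and below them. Cholesterol biosynthesis stood at 1.77, -1.84, -2.19, 0.28 and -0.09 from left to right.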

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

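The tests in this part were chosen after the results were seen, except those on the noise and the bias of probe sets, which were written before.

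The poly-A spike probe sets drew attention because they measure no rat gene, yet their geometric mean was 394.6 on GFP FSH and 539.4 on FOXOA3-mDBD FSH, against 21.4 on GFP vehicle, and a difference in labelling is a candidate explanation for differences that follow this split. It argues against this for part of the steroid pattern that steroidogenesis genes had a median of 0.75 in FOXOA3 FSH against GFP vehicle, and for the cholesterol genes with FOXOA3-mDBD that the median was -2.19, both between arrays of the same spike state. For the cholesterol genes with FOXOA3 it stays open. Their median of -0.085 against GFP vehicle is what a labelling effect and a full block of the FSH response would both give. Scaling as the whole cause is argued against by a median of -1.62 after loess. The cholesterol medians of 1.77 with FSH, -1.84 with FOXOA3 and -2.19 with FOXOA3-mDBD all use the single GFP FSH array. The 2 comparisons without it gave 0.28 and -0.085, inside the random range. These shifts are thus not independent, and an oddity of that array cannot be told from the treatments. The same dependence on that array holds for fatty acid genes (0.72, -0.88 and -0.93) and glycolysis genes (0.83, -0.83 and -0.90). Without it, fatty acid genes were at 0.16 and 0.03 and glycolysis genes at 0.39 and -0.15. All of these lay inside the random range. Cell cycle genes went from 0.77, -1.15 and -1.10 to -0.09 and -0.24, which stood below random lists in the main setting. Of the 1063 genes lower with FSH, 74.98% (797) had both spike-free arrays above both others, but the choice of genes already fixes part of this order, so the share decides nothing; a labelling effect and a FOXOA3 effect that needs DNA binding cannot be told apart there, because they coincide array by array. Among second probe sets of these genes, 66.2% of 296 were higher with FOXOA3 (interval 60.5 to 71.6) against 52.2% of all second probe sets, which argues against a bias of single probe sets as the whole cause.

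Interferon response genes were higher with both FOXO1 vectors than on GFP FSH, and on FOXOA3 FSH than on GFP vehicle. The spike state does not account for the medians within a spike state. These were 1.38 in FOXOA3-mDBD FSH against GFP FSH and 1.17 in FOXOA3 FSH against GFP vehicle, a pair that also differs in FSH. FOXOA3 FSH against GFP FSH crosses the spike state and is not covered by these values. Leukocytes in the cultures stay open: their markers had a median of at most 0.25 in the 2 comparisons within a spike state (0.31 in FOXOA3 FSH against GFP FSH), with upper bounds of 0.78 and 1.13 below the interferon medians of 1.38 and 1.17, but only 4 of 12 measured markers were above 2 times the floor on any array. The written bound was thus met, and it would have excluded leukocytes; a need for 10 such markers was added after these values were seen, because markers near the floor exclude nothing. The amount and preparation of each virus are not given in the sources used here, so a response to the virus and an effect of FOXO1 protein independent of DNA binding may both apply and were not tested.

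The FOXOA3-mDBD FSH array differed most from the others, with an SD of log2 ratios of 1.13 against GFP FSH and 1.17 against GFP vehicle. Noise of single probe sets as the cause is argued against by the correlation between probe sets of the same gene, 0.743, which was above those of the other 4 comparisons (0.614 to 0.708), although the SD per probe set was also the highest at 0.596. RNA integrity stays open, since the GAPDH 3' to 5' ratio was 1.28 times and that of beta-actin 0.890 times that on GFP FSH. A biological effect of the mutant protein was not tested, nor was RNA integrity for the response to FSH, where beta-actin was at 5.15 and 12.0.

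Several named genes had ratios of opposite sign with FOXOA3 and with FOXOA3-mDBD against GFP FSH, each past 2-fold, and the difference was not tested. The log2 ratios were 2.86 and -3.09 for Ccn3, 4.69 and -1.24 for Dcn, and 2.42 and -2.37 or below for Cebpb. They were 2.77 and -1.80 for the matrix protease Adamts5, and -1.03 and 1.09 for Rrm1, a subunit of ribonucleotide reductase. These genes were among 50 that were higher with FOXOA3 and lower with the mutant and 16 that went the other way. Independent lists would give 201 and 82.0 and simulated unchanged arrays 0 and 0.04. Neither is a fit baseline: the comparisons share the GFP FSH array, and the simulation had only 151 to 152 genes in each direction. The split of 50 and 16 genes became 35 and 17 under centring and 25 and 23 under loess. These settings bring the medians of all genes to about 0 and so favour balance by construction. The split itself is not interpreted.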

How the results depend on the processing

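The comparison of FOXOA3 FSH with GFP vehicle was added after the data were seen; the alternatives below were planned. The limits were 1.5 times for a count, the 95% interval for a share, correlation or list median, and the SD per probe set for a gene ratio. Within them stayed 74 of 96 counts, correlations and shares, 883 of 900 list medians and 3180 of 3400 named gene ratios. These limits are wide: they held 1063 and 1564 genes lower with FSH, the latter under the 25th percentile floor, and the more even split into higher and lower genes under centring given below. A list stood apart in a comparison in 51 cases, drawn from 25 lists over comparisons that share arrays. Of these cases, 41 held under all 8 alternatives (42 under the 75th percentile filter, 46 under loess, 47 under quantile normalization, 48 each under the lower floor and the pseudocount, 50 each under centring and the mean of probe sets, 51 without cross-hybridising probe sets). In 8 of the 51 the median was at least 2 times or at most 0.5 times the main one, or of the other sign, in some setting. A 3-fold threshold, which is stricter by construction, left 236 higher and 413 lower with FSH, 426 and 169 with FOXOA3 against GFP FSH, 582 and 742 with FOXOA3-mDBD, and 666 and 379 with FOXOA3 against the mutant. The 25th percentile floor, which admits more genes, gave 1087, 1981 and 1949 higher in the first 3 comparisons, a correlation of -0.22 and 76.6% of FSH-lowered genes higher with FOXOA3. The 75th percentile filter, which admits fewer, gave 695 higher with FOXOA3 against GFP FSH, 1206 against the mutant and a correlation of -0.29. Loess gave 1076 higher with FOXOA3 against the mutant. The share of FSH-lowered genes higher with FOXOA3 was 81.5% in the main setting, 75.2% under loess and 76.8% under centring. Of all genes, 60.2%, 50.5% and 50% were higher in these settings. The share of FSH-raised genes lower with FOXOA3 was 42.6%, 49.7% under quantile normalization, 52.1% under centring and 55.7% under loess. Of all genes, 39.7%, 43.7%, 50% and 49.5% were lower in the same settings, so the passage over 50% followed the scaling, which removes a shift of 0.21 in the median of all genes. Under the 75th percentile filter the share of 43.2% was under the 45.2% of all genes. Centring moved the higher share of 2-fold genes from 39.6% to 50.9% with FOXOA3-mDBD and from 67.2% to 49.9% with FOXOA3 against the mutant (1913 and 932 genes to 1315 and 1319); loess moved them to 53.7% and 45.7%. Cell cycle genes in FOXOA3 against the mutant had a median of 0.0150 under the 75th percentile filter, and Plin2 a log2 ratio of -0.26 with the mean of probe sets; the cause was not tested. No paired analysis was possible because each group had 1 array, which also rules out leaving arrays out in turn. Signals near the floor limit what dim genes can show.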

Other observations

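The signals in this part were chosen after the data were seen, and several are of genes already named in the comparisons. Several genes were far brighter on the FOXOA3-mDBD FSH array than on the other 3. Scel had a signal of 15268 there against 3.0 on GFP FSH, Ranbp17 9745 against 97.3, and Foxq1 3591 against 1.70. On FOXOA3 FSH these genes stood at 451, 168 and 4.90, so that Scel and Ranbp17 were above the floor of 100.5 there. Cnr1 was bright with both FOXO1 vectors, at 4662 and 5193, and stood at 178 and 87.8 on GFP vehicle and GFP FSH.

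On the FOXOA3 FSH array Cyp11a1 had a signal of 9809, against 174 on GFP vehicle, and Hsd17b7 1158 against 848. GFP vehicle is also the array from which the FSH response is read, so these values do not measure how much of that response remained.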
